A study of Homo sapiens with 12 samples.

How the data were processed

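HEK293E cells, a line derived from human embryonic kidney cells, were starved of serum overnight and given 200 nM insulin for 30 h, either alone or after pretreatment with 250 nM Torin1, an inhibitor of the kinase mTOR. Per the labels' protocols, mRNA was selected on poly(A) and either sequenced as input or taken through miCLIP. In miCLIP an antibody against N6-methyladenosine (m6A) is crosslinked to RNA, and substitutions left in the reads mark methylated adenosines. The 12 samples formed 4 groups of 3: insulin input, insulin+Torin1 input, insulin miCLIP and insulin+Torin1 miCLIP. Groups were taken from the sample labels. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

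The submitters' processing notes name the hg38 build, BWA 0.7.1, STAR, DESeq2 1.22.2 and DESeq, without saying which step each was used for. The expression table that the authors deposited held 17520 genes in 6 input libraries. The authors normalized these values between libraries and rounded them before they were deposited, as the grid of values in the file shows, and they were used here as a score rather than as counts of reads. In 5 libraries the low values fell on a grid whose step, the worth of 1 read, lay between 1.03 and 1.70. With that step, 99.1% to 99.9% of the values above 0 came out whole within the rounding of the table, where 58.7% to 97.1% would by chance. In insulin replicate 3 and insulin+Torin1 replicate 2 the chance shares were 95.0% and 97.1%, so this test says little there. In insulin+Torin1 replicate 1 the step was below 1 and was estimated at 0.274 from pile-ups in the value distribution. The steps correspond to 7.32, 9.09 and 11.8 M reads in the insulin libraries and 41.7, 11.1 and 8.20 M reads in the insulin+Torin1 libraries. Because the authors' values were normalized and rounded, no test for raw counts was used, although one had been planned.

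For m6A, the authors deposited 1 list of sites per condition. Each site carried the replicate it was listed under, the number of reads over it, the number of substituted reads and the surrounding 5-mer. The authors computed the deposited value of each site as a fraction, the substituted reads divided by all reads over the site, as the read numbers in the file show. Each position occurred once per list, so how often replicates of 1 condition found the same site could not be computed. All sites carried the DRACH motif (D is A, G or T; R is A or G; H is A, C or T), so the planned comparison of DRACH shares was void. A transcript annotation was not used here, and the planned share of sites in the 3' UTR was not computed. The share within 2000 nt of the annotated end of the gene took its place, a choice made after the data were examined.

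Expression was tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend in the variance, for genes with a value of at least 10 in at least 3 libraries. Fold changes are on that scale, which understates the change of low genes. Benjamini-Hochberg adjusted p-values from limma below 0.05 were called, and a second test asked for a change beyond 1.5-fold. Of 33 gene lists fixed before the data were examined, 29 had at least 5 tested members. These were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation was run beside it. Tested on simulated data for 3 against 3 libraries, the procedure called 0 of 13728 genes when none was changed. With 200 changed genes planted it called 4 of 13546 unchanged genes and recovered 40.0%, 64.0%, 85.4% and 100% of genes changed by 0.2, 0.5, 1 and 2 on the log2 scale. On the simulated libraries without changed genes, 5 of 200 random lists had a camera p below 0.05. Genes were drawn independently there, so this check cannot show how camera behaves on lists of correlated genes.

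Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups. From each list that passed camera it took up to 4 called members, those with the largest log2 fold change in the list's direction. It also took all tested members of the MAX network and m6A machinery lists. For m6A it took the 5 genes with the most sites in each list, the 5 with the largest gain and the 5 with the largest loss, and the 3 sites with the highest substituted fraction per list. Ties were broken by the number of reads.

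Sites were assigned to gene bodies of the RefSeq annotation of GRCh38, which gave 96.9% of the table's symbols a position. In the insulin list 85.8% of sites and in the Torin1 list 86.1% lay in exactly 1 protein-coding gene. The annotation used carried no strand, so a gene's strand was that of most of its sites. In the 4926 genes with 10 or more sites, 95.9% of sites lay on that strand. That share cannot reveal a wrong strand, which a gene gets when most of its sites belong to an antisense gene. Sites in several protein-coding genes were not assigned, so a gene that overlaps another can show too few sites. Sites at the same chromosome, position and strand were counted as shared. Shares are given with Wilson 95% intervals, which cover counting error only since reads are not independent molecules. Intervals of differences come from 1000 bootstrap draws over genes, or 500 for substituted shares, and use the sites assigned to a gene. Site tables were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

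The alternatives were other filters, a replicate block, leaving out each library in turn, an estimated inter-gene correlation, other criteria for sites, and matched reference genes. Scaling to equal totals, quantile normalization, pseudocounts of 0.5 and 5, and weights from the recovered reads were added after the data were examined. The planned second normalization by size factors was already in the values.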

Results

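The data ask what inhibition of mTOR does to mRNA levels and to the m6A map of insulin-treated HEK293E cells. Expression values were available for 3 libraries with insulin and 3 with insulin and Torin1. Their totals were 12424643 to 12528454 normalized units with insulin and 11418114 to 11438881 with Torin1, and the recovered depth was 7.32 to 41.7 M reads. The m6A lists held 96671 sites with insulin and 63578 with insulin and Torin1.

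Most of the measured transcriptome differed between the libraries with Torin1 and those with insulin alone. DHRS2, which encodes a mitochondrial reductase, fell from 10184 ± 740 normalized units with insulin to 113 ± 11.5 with Torin1 (mean ± SD, n = 3 each), a log2 fold change of -6.48. ACSBG1, an acyl-CoA synthetase gene, fell from 1308 ± 79.3 to 8.33 ± 2.31, and the transcription factor gene EGR3 fell from 1002 ± 40.7 to 18.7 ± 3.51. SLC7A11, which encodes the cystine transporter, fell from 4000.3 ± 149.6 to 169 ± 1.53. The other large falls were in SPOCK2, C1S, WFIKKN1, CHAC1, RFTN2 and EGR1, with log2 fold changes from -4.81 to -4.07.

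Among the rises, VCAN, which encodes the matrix proteoglycan versican, went from 163 ± 20.9 to 2732 ± 33.8 units, a log2 fold change of 4.07 (n = 3 each). NCAM1, a cell adhesion gene, rose from 40.0 ± 2.65 to 706 ± 25.8. SPATA18 rose by 4.49, ASB13 by 4.44 and CC2D2A by 4.28 on the log2 scale, and TTC5, DNAJC18, TMEM132A and APH1B by 3.81 to 3.90. With limma at an adjusted p below 0.05, 6010 of 13842 tested genes were higher and 5888 lower with Torin1. A change beyond 1.5-fold was called for 3462 genes upward and 3115 downward. The 3 Torin1 libraries lay beyond all 3 insulin libraries in 86.3% of tested genes, where chance gives 10%. Squared differences between replicates were 1.09 to 1.24 times what sampling of reads gives, for genes with summed values of 50 to 1000. For summed values over 5000 they were 3.46 to 4.87 times. Replicates this close may share a culture, in which case these calls do not measure the spread between cultures. Scaling to equal totals moved the median log2 fold change of all genes by 0.12 and called 6681 genes higher and 5281 lower (3934 and 2635 beyond 1.5-fold), and quantile normalization reversed 125 calls. Fold changes are given without either.

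Genes of amino acid supply and stress signalling were lower with Torin1. Of 26 tested genes of amino acid synthesis and targets of the transcription factor ATF4, 24 fell and 0 rose, with a median log2 fold change of -1.80. Examples were SLC7A11 at -4.55, CHAC1 at -4.32, CTH at -3.23 and TRIB3 at -3.10. Of 15 genes of the unfolded protein response, 14 fell, among them EDEM1 at -2.35, HERPUD1 at -2.32, XBP1 at -1.98 and DNAJB9 at -1.81. Of 17 immediate early and ERK feedback genes, 14 fell and 3 rose; EGR3 changed by -5.69, FOS by -4.08, EGR1 by -4.07 and JUNB by -3.37. Camera with the preset correlation gave adjusted p = 1.3e-09 for the amino acid list, 6.1e-06 for the unfolded protein response and 0.0021 for the immediate early list. The adjusted p with an estimated correlation was 0.161, 0.103 and 0.272, so none of these list calls held.

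Lipid and DNA synthesis genes fell as well. Of 24 genes of cholesterol synthesis and uptake, 20 fell and 1 rose, with HMGCS1, which encodes a synthase early in the pathway, at -2.24, ACAT2 at -1.96, INSIG1 at -1.93 and IDI1 at -1.76. Of 27 DNA replication genes, 23 fell and 2 rose, with E2F1 at -1.79, TK1 at -1.76, CCNE2 at -1.70 and CDC6 at -1.64. Of 13 fatty acid synthesis genes, 10 fell and 2 rose, with SREBF1 at -1.32, ACACA at -1.11, ME1 at -1.05 and ELOVL5 at -0.65. Camera gave adjusted p = 2.8e-05 for cholesterol, 2.4e-05 for DNA replication and 0.0480 for fatty acid synthesis. With an estimated correlation the adjusted p was 0.103, 0.161 and 0.223, and fatty acid synthesis was not called by camera without insulin replicate 3 (adjusted p = 0.0584) or Torin1 replicate 1 (0.0514) or 3 (0.0564). With scaling to equal totals it was at -0.29 (camera adjusted p = 0.0693) and with quantile normalization at -0.18 (0.253).

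Degradation genes and tRNA synthetase genes were also mostly lower. Of 25 autophagy genes, 19 fell and 4 rose; TP53INP2 changed by -2.29, MAP1LC3B by -2.06, ATG4A by -1.73 and GABARAPL1 by -1.68. Of 32 proteasome genes, 23 fell and 5 rose, including falls of PSMC4 (-1.64), PSMB3 (-1.44), PSMB2 (-1.05) and PSMD14 (-1.03). Of 20 cytosolic aminoacyl-tRNA synthetase genes, 14 fell and 4 rose, including falls of GARS (-1.96), WARS (-1.91), CARS (-1.56) and TARS (-1.40). Camera gave adjusted p = 0.0016 for autophagy, 0.0021 for the proteasome and 0.0411 for the synthetases. With an estimated correlation the adjusted p was 0.161, 0.161 and 0.403. The median of the synthetases was -0.31, but -0.19 with scaling to equal totals (camera adjusted p = 0.0693) and -0.09 with quantile normalization (0.492).

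Ribosomal protein mRNAs moved the other way. Of 84 tested cytosolic ribosomal protein genes, 73 rose and 6 fell, with a median log2 fold change of 0.66. RPL15 rose from 2219 ± 99.4 to 12710.3 ± 98.5 units (n = 3 each), a log2 fold change of 2.52, and RPL22, RPS27L and RPL29 changed by 2.01, 1.83 and 1.81. RPL3L (-4.32) and RPL21 (-1.53) were lower. Many of these genes have processed pseudogenes that can take part of their reads. All 13 mitochondrially encoded mRNAs rose, with MT-CO2 at 0.85, MT-CO3 at 0.76, MT-ND6 at 0.68 and MT-ND5 at 0.66. Of 24 mitosis genes, 17 rose and 4 fell, with KIF20A at 1.99, BUB1B at 1.87, PLK1 at 1.65 and BIRC5 at 1.60, while MKI67, the proliferation marker, was at -0.86. Camera gave adjusted p = 6.3e-12 for ribosomal proteins, 8.1e-04 for mitochondrial mRNAs and 0.0021 for mitosis. With an estimated correlation the adjusted p was 0.216, 0.446 and 0.161, and with quantile normalization the mitochondrial median was 0.22 (camera adjusted p = 0.0714).

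**Figure D1:**
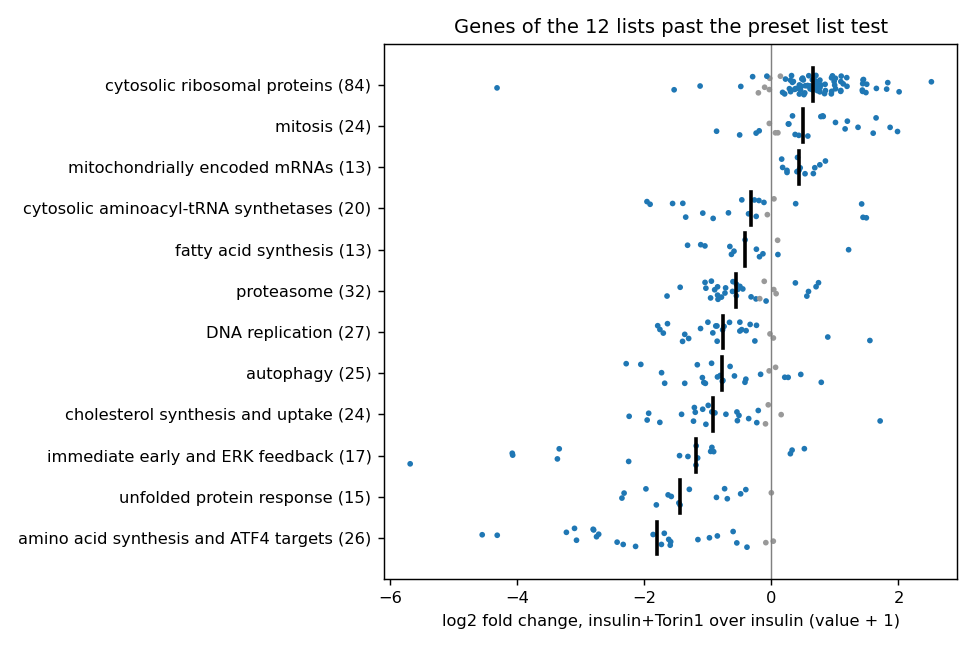
Each point is 1 gene of the 12 lists that passed camera with the preset correlation, with the number of tested genes in brackets. The x axis is the log2 fold change of insulin+Torin1 over insulin, blue points passed limma at an adjusted p below 0.05, grey points did not, vertical position within a list is random, and black bars are medians, from -1.80 for amino acid synthesis to 0.66 for ribosomal proteins.

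The other 17 tested lists did not pass camera, although hypoxia response passed with no filter beyond a value above 0 (adjusted p = 0.0336) and purine and pyrimidine synthesis with quantile normalization (0.0121). Of 15 hypoxia response genes 10 fell and 1 rose, and of 18 MYC-activated genes 10 fell and 5 rose. In ribosome biogenesis 16 of 26 genes fell and 6 rose, and in glycolysis 12 of 19 fell and 5 rose. Of 24 mTOR pathway and translation initiation genes 12 fell and 7 rose, of 39 lysosomal genes 21 fell and 17 rose, and of 20 FOXO target and insulin receptor feedback genes 12 fell and 7 rose. Of 18 purine and pyrimidine synthesis genes 12 rose and 5 fell, of 66 nuclear-encoded oxidative phosphorylation genes 32 rose and 27 fell, and of 15 p53 targets 8 rose and 4 fell. In the methionine cycle 6 of 11 genes fell and 4 rose, in mRNA deadenylation and decay 11 of 20 fell and 7 rose, and in the pentose phosphate pathway 4 of 7 rose and 2 fell. Of 12 interferon-stimulated genes 6 rose and 4 fell, and of 29 replication-dependent histone genes 8 rose and 8 fell. Adjusted over the list alone, 80 rather than 79 ribosomal protein genes, 18 rather than 17 purine and pyrimidine genes and 14 rather than 16 histone genes were called, and the other counts were the same. Markers of other cell types were scarce, with 3 of 10 blood cell markers, 3 of 9 fibroblast and endothelial markers and 0 of 6 keratinocyte and hepatocyte markers passing the filter on low values. Of these, CD14 (-4.61) and HBA1 (-3.35) fell and COL3A1 (2.57) and COL1A1 rose.

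The MAX network, transcription factors that pair with MAX or MLX and include MYC and its antagonists, shifted in both directions. MYC rose from 339 ± 37.9 to 1292 ± 42.0 units (n = 3 each), a log2 fold change of 1.93. MLXIPL rose by 1.29, MYCL by 0.91 and MXI1, which encodes a MYC antagonist, by 0.76. MXD1, another antagonist gene, fell from 1107 ± 37.7 to 269 ± 15.6, a log2 fold change of -2.04. MGA was at -0.94, MNT at -0.88, MAX at -0.73, MLX at -0.67, MXD4 at -0.37 and MLXIP at -0.24, all called, while MXD3 at 0.09 was not (limma adjusted p = 0.147). With quantile normalization MXD4 (-0.08) and MLXIP (-0.03) were not called, and with scaling to equal totals MXD3 was called at 0.22. Camera gave adjusted p = 0.432 for the network as a list.

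Of 21 genes for m6A writers, erasers and readers, 14 fell and 6 rose. RBM15, a writer complex gene, fell from 1618 ± 79.6 to 536 ± 27.6 units (n = 3 each), a log2 fold change of -1.59, and ALKBH5, which encodes a demethylase, fell from 2581 ± 77.2 to 865 ± 9.87, a change of -1.58. The methyltransferase gene METTL14 fell from 1472 ± 69.5 to 736 ± 7.77, while METTL3 was at 0.27 and METTL16 at -0.64. Among writer complex genes, WTAP was at 0.47, KIAA1429 at -0.61 and CBLL1 at -0.51. RBM15B at -0.23, ZC3H13 at -0.15 and the reader gene YTHDC1 at -0.13 were called lower, but with quantile normalization YTHDC1 was called higher at 0.16, and RBM15B and ZC3H13 were at 0.02 and 0.07 and not called. Without Torin1 replicate 3 YTHDC1 was at -0.09 and not called. The demethylase gene FTO was at 0.81. Reader genes ranged from YTHDF2 at -0.85 to HNRNPA2B1 at 0.88, with YTHDC2 at 0.81, IGF2BP3 at -0.52, YTHDF1 at -0.49, IGF2BP1 at -0.41, YTHDF3 at -0.28 and HNRNPC at 0.17. IGF2BP2 at 0.05 was not called. With scaling to equal totals IGF2BP2 was called at 0.17 and ZC3H13 (-0.03) and YTHDC1 were not called, and with quantile normalization YTHDF3 (-0.01) was not. Camera gave adjusted p = 0.164 for this list.

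Of the m6A sites in the insulin list, 27378 were also in the Torin1 list, which is 28.3% (Wilson 95% interval 28.0% to 28.6%) of the insulin list and 43.1% of the Torin1 list. In genes with at least 10 CPM in both groups the shares were 31.5% and 48.9%. The lists differed mainly in replicate 2, with 39670 sites with insulin and 1552 with Torin1, while replicate 1 held 50656 and 56298 and replicate 3 held 6345 and 5728. Without the Torin1 replicate 1 sites, 2.53% of the insulin list was shared. Each position is listed under 1 replicate, so these numbers may not be the yield of each library. Between the sites listed under replicate 1, 32.1% of insulin sites recurred, rising from 23.3% of sites with 1 substituted read to 91.9% of those with 10 or more.

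**Figure D2:**
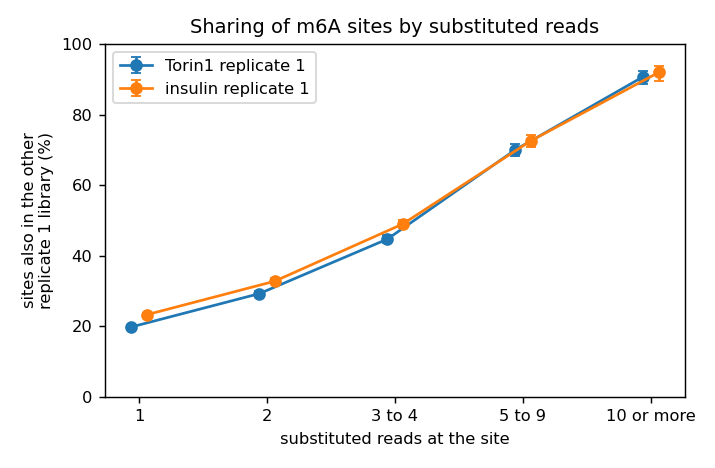
The share of m6A sites in 1 replicate 1 library that were also listed in the replicate 1 library of the other condition (y axis, percent) is plotted against the number of substituted reads at the site (x axis), with Wilson 95% intervals. Sharing went from 23.3% to 91.9% for insulin sites and from 19.8% to 90.7% for Torin1 sites.

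SPEN, which encodes a transcriptional repressor (chromosome 1, 15847707 to 15940456, hg38), had 118 sites with insulin and 97 with Torin1, but 74 and 88 under replicate 1. MKI67 (chromosome 10, 128096659 to 128126423) had 116 and 56, and SON and SRRM2, which encode splicing factors, had 95 and 64 and 95 and 55. Under replicate 1 MKI67 had 64 and 49, SON 63 and 59, and SRRM2 62 and 50. EEF2, which encodes a translation elongation factor (chromosome 19, 3976056 to 3985463), had 45 and 55. The largest losses were in PRR14L (chromosome 22, 31681347 to 31750132), with 102 and 12 sites, MAP1B (chromosome 5, 72107475 to 72209565), with 99 and 11, ZNF292, with 90 and 23, and PEAK1, with 101 and 37. Under replicate 1 PRR14L had 59 and 10, MAP1B 60 and 10, ZNF292 38 and 19, and PEAK1 62 and 32.

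VCAN had the largest gain of m6A sites, from 2 with insulin to 41 with Torin1 (chromosome 5, 83471744 to 83582302, hg38). CELSR1 went from 4 to 26, SLITRK5 from 11 to 29 and PLXNB2 from 12 to 28. TTN was also among the largest gains, with 8 and 35 sites. These lay on the plus strand, opposite to TTN and in a region shared with its antisense gene. The strand rule counted them under TTN in the results per gene, although they are not sites of TTN mRNA. In the MAX network MYC had 9 and 21 sites, MGA 48 and 16, MNT 23 and 5, MLXIP 26 and 9, and MXI1 6 and 1. Under replicate 1 MYC had 6 and 18, MGA 24 and 13, MNT 13 and 5, MLXIP 13 and 9, and MXI1 3 and 1. In the machinery genes RBM15 had 39 and 24, RBM15B 36 and 23, ALKBH5 14 and 4, METTL14 11 and 8, FTO 5 and 5, KIAA1429 14 and 15, and HNRNPA2B1 14 and 17. Under replicate 1 METTL14 had 3 and 8, FTO 2 and 5, RBM15B 21 and 21, RBM15 30 and 24, ALKBH5 10 and 4, KIAA1429 6 and 13, and HNRNPA2B1 8 and 17. The body of WTAP, which overlaps SOD2, held 14 and 16 plus-strand sites that were not assigned. These numbers come from 1 list per condition and have no replicate test.

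All reads were substituted at 13.9% of insulin replicate 1 sites and 9.41% of Torin1 replicate 1 sites. Named here are the 3 such sites with the most reads in each list. In the insulin list all 157 reads at chromosome 3, 174377845 in RPL8P4 and all 53 at chromosome 6, 27652652 in RPL8P1 were substituted, both processed pseudogenes of RPL8. The third was chromosome 3, 142827346 in PCOLCE2, with 35 of 35 reads. In the Torin1 list the top sites were chromosome 3, 142827255 in PCOLCE2 with 76 of 76 reads, chromosome 1, 88857300 in GTF2B with 28 of 28, and chromosome 7, 6023651 with 19 of 19. All 6 positions were in both lists.

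The 4-mer GGAC opened 31.5% of insulin and 32.9% of Torin1 sites. Among sites assigned to a gene the difference was 1.60 points (bootstrap 95% interval 1.195 to 2.02). Between the replicate 1 libraries alone the shares were 33.4% and 33.3%, and among sites in genes the difference was 0.0261 points there, 0.113 without insulin replicate 2 and -0.906 without Torin1 replicate 1, with intervals reaching 0. Within 2000 nt of the annotated end of the gene lay 31.4% of insulin and 32.8% of Torin1 sites, a difference of 1.46 points (0.915 to 2.02). Between the replicate 1 libraries this difference was 0.510 points (-0.0946 to 1.17), and it was 0.552 without insulin replicate 2 and 0.385 without Torin1 replicate 1, with intervals reaching 0. Among replicate 1 sites with 3 or more substituted reads it was 3.23 points (1.75 to 4.61), and the GGAC difference in genes was 1.18 points (0.0468 to 2.34). Within 5000 nt the replicate 1 difference was -1.44 points (-2.17 to -0.679). The values without a replicate leave out positions listed under it that other replicates may also have found.

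Genes carrying m6A sites in either list had a mean log2 fold change of 0.04 (11490 genes), against 0.22 for 2352 genes without an assigned site. The difference of -0.18 did not pass camera with the preset correlation (p = 0.137) and did with an estimated correlation (p = 0.0064), a call that was lost with scaling to equal totals, quantile normalization and matched reference genes. An exact permutation of the 6 libraries gave p = 0.1, the smallest that 3 against 3 allows, two-sided. Against 1588 genes with a matched gene body and no site on either strand the difference was -0.23, and against genes matched on expression and gene body length it was -0.07. Genes with sites in the insulin list differed from all others by -0.60 and passed camera with either correlation, while genes with sites in the Torin1 list differed by 0.17 and passed with neither. The difference was -0.02 with no filter beyond a value above 0 and -0.04 with quantile normalization. Genes with sites only in the insulin list had a mean of -0.48 and those only in the Torin1 list a mean of 1.19, against -0.01 for genes in both lists. From genes with 1 to 2 sites to those with over 20, counted over both lists, the median log2 fold change went from 0.33 to -0.44. Finding a site needs reads of the mRNA, so expression and site detection are not independent in these classes.

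**Figure D3:**
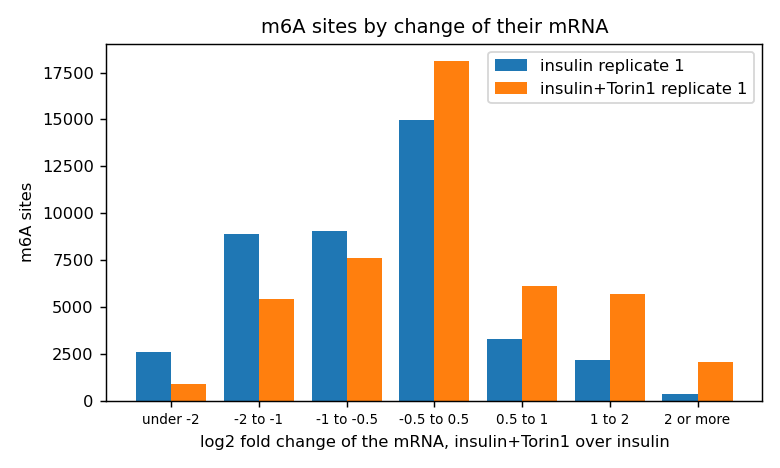
Bars give the number of m6A sites in the replicate 1 library of each condition (y axis), for genes grouped by the log2 fold change of their mRNA, insulin+Torin1 over insulin (x axis). Genes that fell by more than 2 held 2589 insulin and 886 Torin1 sites, and genes that rose by 2 or more held 376 and 2063.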

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

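The pseudocounts, scalings, weights, miCLIP library choices, sites with 3 or more substituted reads, the stricter reference for m6A genes and the estimated correlation for m6A genes were chosen after the data were examined. Limma called 11898 genes, 11459 to 11810 without single libraries and 6577 when the test asked for 1.5-fold, which is stricter by construction. The count beyond 1.5-fold was 6266 to 6514 without single libraries. Camera called 12 lists, 11 to 12 without single libraries and 0 with an estimated correlation, where 7 had an unadjusted p below 0.05. For the unfolded protein response, fatty acid, cholesterol and autophagy lists the estimated correlation was -0.036, -0.012, -0.0050 and 0.00023. These lie below the preset 0.01, so a higher correlation does not explain the loss of these calls. In the other passing lists it was above 0.01, but for mitosis only slightly, at 0.0102. The unadjusted camera p for mitosis still went from 7.1e-04 with the preset to 0.0278 with the estimated correlation. Camera with an estimated correlation thus differs from camera with the preset in more than the correlation. The loss of calls cannot be read as an effect of correlated genes alone. The cause was not tested. Deviations of same-numbered libraries from their group means had correlations of -0.145, -0.016 and -0.088 over 9505 genes. They gave no sign that replicate numbers pair the samples but cannot exclude it, and a replicate block gave 11850 genes. With quantile normalization RBM15B changed to 0.0195, ZC3H13 to 0.0660 and YTHDC1 to 0.16; the cause was not tested. The difference between genes with and without m6A sites was -0.18 and passed with an estimated correlation, and it was -0.39 and passed for genes with at least 3 sites. It was -0.02 with no filter beyond a value above 0, -0.04 with quantile normalization and -0.07 against genes matched on expression and gene body length, none passing with the preset correlation. With the estimated correlation the call was lost with quantile normalization, scaling to equal totals (-0.18) and matched genes, and kept with no filter; the cause was not tested. It was -0.23 against genes with no site in their body, passing with the estimated correlation and not with the preset one, and -0.19 to -0.17 without single libraries. The shared part of the insulin list, 28.3%, was 29.0% within 5 nt, 9.76% in the upper 0.5 of substituted shares, 21.4% at equal list length, 31.5% in expressed genes, 32.1% in replicate 1 and 51.5% with 3 or more substituted reads. High substituted shares can rest on few reads. All reads were substituted at 13.9% of sites in insulin replicate 1 (median 9 reads) and 45.7% in insulin replicate 3 (median 2 reads). It was 2.53% to 33.1% without single miCLIP libraries, lowest without Torin1 replicate 1. The GGAC difference was -0.109 points in replicate 1 and -1.19 to 3.41 without the sites listed under single replicates. Over all sites it was negative without insulin replicate 2 or Torin1 replicate 1. Among sites in genes it was 0.0261 in replicate 1, 0.113 without insulin replicate 2 and -0.906 without Torin1 replicate 1, with intervals reaching 0. The difference near the gene end was 0.510 points in replicate 1 and 0.385 to 2.70 without the sites listed under single replicates. Its interval reached 0 without insulin replicate 2 or Torin1 replicate 1. For these site results the cause was not tested. Of 435 alternatives for single lists 413 and of 1358 for named genes 1347 kept direction and side of the threshold. A count test and thinning of reads were not run because raw reads were not used here, and the 3' UTR and DRACH results have no value. Sites with few substituted reads limit the m6A lists.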

Other observations

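Genes in the mTOR pathway itself, chosen here after their values were seen, went in both directions with Torin1. TSC1, which encodes a negative regulator of mTOR complex 1, changed by -3.04 on the log2 scale while its partner TSC2 changed by 1.09. AKT1S1 changed by -2.01, RHEB by -1.20 and RICTOR by -0.91. The translation factor genes EIF4A2 and EIF4B changed by 2.23 and 1.07, EIF4A1 was at 0.08 (limma adjusted p = 0.521) and EIF4E at 0.03 (limma adjusted p = 0.749). In nucleotide synthesis CAD was at 2.09, PRPS2 at 1.73 and IMPDH2 at 1.21, and PPAT at -0.79. Although MYC mRNA rose, the MYC-activated genes TFRC (-2.07), CCND2 (-1.73) and ODC1 (-1.11) were lower and APEX1 (0.88) and NME1 (0.82) higher.

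In the paragraphs that follow, the tests of site numbers by replicate, the dilution test on sites with 20 or more substituted reads and the split test for genes were chosen after the result was seen. The Torin1 list was shorter than the insulin list, 63578 against 96671 sites. The ratio of sites per read cluster, Torin1 over insulin, was 0.812 in replicate 1, 0.625 in replicate 2 and 1.39 in replicate 3. Each position is listed under only 1 replicate, so these ratios cannot decide whether the yield was lower with Torin1, which stays open. Uneven depth of the replicates is a candidate explanation: replicate 1 listed 1.11 times as many sites with Torin1 as with insulin, and the lists differed most in replicate 2. How positions found in several replicates were assigned is not known, so these numbers may not be the yield of each library.

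The number of m6A sites per gene followed the mRNA. Across 5793 genes with 5 or more replicate 1 sites, which are not independent replicates, Spearman's rho between the log2 ratio of site numbers and the log2 fold change was 0.637. In 513 genes whose mRNA changed by less than 0.2, site numbers scattered no more than counting of independent sites allows, with a variance ratio of 0.898 (bootstrap 95% interval 0.790 to 1.03), where a value above 1.5 would have spoken against abundance as the whole cause. The 2 libraries had 16264 positions in common, which lowers the scatter. A ratio near 1 therefore does not show that abundance is the whole cause. A candidate explanation for gains such as VCAN (mRNA 4.07) and losses such as PRR14L (mRNA -3.24) is the change in mRNA level. A change of methylation in single genes stays open, because 1 library per condition was compared.

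At 16264 m6A sites shared between the replicate 1 libraries the substituted share was lower with Torin1, with a median log2 ratio of -0.78. The Torin1 library was read more deeply there, with a median of 36 reads per site against 20 with insulin. At sites with 100 or more reads in both libraries the medians were 282 and 155 reads, and the median log2 ratio was -0.76. Over all 14087 shared sites in tested genes, the ratio in genes that rose minus that in genes that fell was -1.47. This met the expectation for dilution set before this test was run. But at sites with 1 substituted read in each library, where the share is set by the reads alone, the gap was -2.58. The comparison over all shared sites therefore decides nothing. At sites with 20 or more substituted reads in sum the median was -0.62 and the gap was 0.44 (0.04 to 0.74), but choosing sites by their substituted reads in insulin or in Torin1 alone moved the median from -1.08 to -0.28, so dilution by reads of mRNAs that rose stays open. In genes whose mRNA changed by less than 0.2 the median was -0.93 over 2417 shared sites and -0.68 over 76 sites with 20 or more substituted reads. At sites with 1 substituted read in each library, where the reads alone set the share, these genes had a median of -1.14. The 76 sites were chosen by their substituted reads. The lower share was also seen where the mRNA changed little, with 1 library per condition. These limits keep it from deciding for or against dilution. Selection of sites stays open, since sites with 10 or more substituted reads in Torin1 gave -0.28, between the bounds set for it (0 and -0.3). A factor of the whole library may be involved, as all 18 5-mers with 20 or more sites had medians of -0.52 or lower, and whether it is technical or an effect of Torin1 on methylation cannot be told apart with 1 library per condition.

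The 6 input libraries can be split in 10 ways, too few for a share under 0.05. The real split called 11898 genes and was 1 of 10 splits with a count as large; the highest other split called 0 by limma. For the lists, 3 of 10 splits called at least the real 12, and the highest other called 13. Each other split leaves part of the Torin1 difference between its groups and puts the rest into the spread within them. With most genes differing between the conditions, this wider spread made low gene counts in the other splits likely beforehand. The contrast of 11898 with 0 therefore does not measure chance. For the difference between genes with and without m6A sites, 1 of 10 splits was as large, with 0.18 in size for the real split and 0.07 for the highest other.

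Sites in pseudogenes were 4 of 14 insulin sites (28.6%, Wilson 95% interval 11.7% to 54.6%) with at least 10 reads and a substituted share of at least 0.9. Among 39079 insulin sites with a share under 0.5 they were 1.03%. In the Torin1 list the numbers were 3 of 17 and 1.16% of 32909.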
